A study of Arabidopsis thaliana with 6 samples.

How the data were processed

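Transcript levels were measured on Affymetrix ATH1 arrays in 6 samples of Arabidopsis thaliana, accession Landsberg erecta, from 6-week-old plants. Each sample was pooled from 12 plants, and there were 3 groups of 2 arrays: closed buds, open pollinated flowers, and siliques 2 d after pollination. The submitters' processing notes name MAS5 as the tool and give no version, settings or detection calls. The deposited values are MAS5 signal intensity on a linear scale, 1 value per probe set. The deposited intensity of every array has a 2% trimmed mean of 100.01, so all arrays share a scale. The number of arrays limits the precision.

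The table held 22810 probe sets, of which 64 were controls and stayed out of every test. Gene identities came from the gene tables supplied with the reference: 13513 probe sets were paired with a single gene, and 13436 of these matched the RefSeq gene table. Another 503 were paired with several genes and 8730 with no listed gene. A probe set was tested if its signal reached 50 on at least 2 arrays; 12075 passed and 10671 were below. Among those tested, 6315 belonged to a single gene, covering 6275 genes, of which 967 carried a symbol. Most classical floral regulators had no listed probe set of their own, so the gene lists are thin and a gene absent from the text was often not identified among the probe sets rather than unchanged.

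Signals were offset by 10 and log2 transformed. Linear models were fitted in limma 3.58.1 under R 4.3.3 with lmFit, contrasts.fit and eBayes with an intensity trend. The models used all 6 arrays, 3 groups and no further normalization, which left 3 residual degrees of freedom and a median prior of 3.61. Two-sided p values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. In the text, ± after a signal is the SD of 2 arrays and ± after a log2 change is limma's standard error. Where both arrays of the dimmer group lay at or below the highest control probe set without a spiked-in target (7.20 to 10.1 by array), the fold is given as a lower bound against that level. That bound uses signals without the offset, so it can exceed the fitted fold, and it carries no error.

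The replicate numbers pair the samples, because the labels say that the complete experiment was carried out a second time. The pairing was checked as the correlation, across probe sets, of the replicate 1 minus replicate 2 differences of each pair of groups. These were 0.34 for buds and flowers, −0.01 for buds and siliques and 0.17 for flowers and siliques. Replicate was left out of the main model and added as a term in an alternative.

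Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, using 1 probe set per gene, the brightest, and at least 3 measured members. The 18 lists, the test, the named-gene rule and the alternatives were fixed before the data were examined. Of the 344 list genes, 70 were paired with a probe set of their own and 42 were tested; 7 lists reached 3 members. Lists for the female gametophyte and endosperm, embryo and seed maturation, meristem and cytosolic ribosomal proteins had no tested member. Because the lists were thin, 42 further groups were set up from the gene symbols of probe sets that passed the filter, 18 by hand and 24 as families sharing a symbol stem. These were chosen after the gene table was seen and before any test, and are called added groups; they were adjusted as a family of their own. Only added groups past the threshold in at least 1 comparison are described, except the jasmonate genes.

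Genes were named by rule. In each comparison these were the 6 largest rises and the 6 largest falls among called genes with a symbol whose arrays did not overlap between the groups, and up to 4 called members of each list. A further 15 marker genes were to be named always, but in the supplied gene table only AGL62 was paired with a probe set of its own, and its signal (4.45 to 12.2) was below the filter. Members that are named although they did not pass, genes beyond the first 4 of a list, and genes named in the account of opposite changes were chosen after their values were seen.

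The analysis was tested on simulated data with 200 of 12075 probe sets changed, 10 times per comparison. For flowers against buds, 60.5% of 2-fold and 97.8% of 4-fold changes were recovered, and 6.61% of calls were false. The corresponding values were 59.6%, 98.0% and 6.64% for siliques against flowers, and 58.5%, 97.5% and 5.68% for siliques against buds. The false share was thus somewhat above the nominal level. The simulated noise was drawn independently for each probe set from its fitted spread, with no effect of run and no link between genes. Fewer probe sets were changed than were called in the data, so these rates need not hold for the real calls. Shared calls were set beside 100 simulations that kept the called changes and the spread of each probe set, and dealt the changes of siliques against flowers out anew among probe sets of like spread (10 bins). A planned simulation with no change in any group makes almost no calls, so it says nothing about shared ones.

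The alternatives were smaller and larger offsets, no filter and a stricter filter, quantile, median and cyclic loess normalization, and a replicate term. Others used only the arrays compared, a fit without the trend, a robust fit, stricter thresholds, the mean of all probe sets of a gene, an estimated correlation, and each array left out in turn. After the counts were seen, shared calls were also counted with 1 flower array set against buds and the other against siliques, in both ways round. With 1 array left in a group, its spread is assumed to be that of the other groups. Groups of 2 arrays allow no test of other splits of the samples and no outlier test. Raw array images and detection calls were not used here.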

Results

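Transcript levels were measured in whole closed buds taken shortly before pollination, whole open pollinated flowers, and siliques harvested 2 d after pollination without the withering flower organs. Each stage had 2 independent arrays, and flowers 1, for example, is the flower array of replicate 1. The organs present differ between the stages by design, so each difference covers both the organs harvested and the expression within them. Median signals ran from 41.5 to 48.3, and 10455 to 11192 probe sets per array reached a signal of 50. Log2 signals correlated at r = 0.936 to 0.963 in the 3 pairs of arrays of the same stage and at 0.733 to 0.870 in the 12 pairs of different stages. Buds lay apart along the first principal component (53.3% of the variance) and flowers along the second (33.2%). The ratio of 3' to 5' signal for GAPDH, a measure of RNA integrity, was 0.967 and 1.02 on the flower arrays and 0.835 to 0.919 on the others, but those for actin (1.34 and 1.41 on the flower arrays, 1.19 to 1.38 on the others) and ubiquitin (1.304 and 1.303, against 1.17 to 1.51) did not set the flower arrays apart in the same way. The spiked-in hybridisation controls of siliques 2 stood at 1.78 times the level of the other arrays.

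Open flowers were compared with closed buds to find which transcripts differ between the stages just before and just after the flower opens and is pollinated. Among genes with a symbol, the largest fitted rise was in CYP71B31 (AT3G53300), a cytochrome P450, at 1839 ± 204 (SD, n = 2) in flowers and 11.9 ± 16.5 (SD, n = 2) in buds, a log2 change of 6.64 ± 0.50 (adjusted p = 0.000694). Its size is uncertain, because the bud arrays were at 23.5 and 0.24. It was 5.78 without buds 2 and 7.49 without buds 1. SWEET9 (AT2G39060), the sugar exporter of nectaries, rose from 28.1 ± 26.7 to 1405 ± 189 (log2 change 5.41 ± 0.46, adjusted p = 0.00101). With 1 array left out its change ran from 4.63 to 6.19, which overlaps that of CYP71B31. ATA27 (AT1G75940), a beta-glucosidase gene known from anthers, fell from 1510 ± 100 in buds to 25.1 ± 34.6 in flowers (log2 change −5.91 ± 0.70, adjusted p = 0.00331; −7.15 to −4.67 with 1 array left out). AT5G07230, entered in the list as the tapetum gene A9, was at least 95.3-fold lower in flowers, with a signal of 876 ± 457 in buds and 1.43 ± 0.22 in flowers. In all, 547 probe sets were higher and 740 lower in flowers than in buds (567 and 548 without buds 1).

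The other large rises were LPR1 (AT1G23010), a multicopper oxidase, at 586 in flowers and 14.7 in buds, UPB1 (AT2G47270), a transcription factor, at 478 and 26.9, and XTH19 (AT4G30290), a cell wall xyloglucan enzyme, at 290 and 11.9. Their log2 changes were 4.60 ± 0.23, 3.80 ± 0.37 and 3.80 ± 0.29. DELTA-VPE (AT3G20210), a vacuolar processing enzyme, was at 264 ± 35 in flowers and 14.4 ± 5.1 in buds (adjusted p = 0.000557). Among the large falls, SHT (AT2G19070), which conjugates spermidine in the tapetum, was at least 35.2-fold lower, and ATOEP16-2 (AT4G16160), a plastid envelope protein, at least 14.7-fold lower. LEA (AT2G21490), sks18 (AT1G75790) and AtVEX1 (AT5G62850) had log2 changes of −4.35 ± 0.64, −3.99 ± 0.36 and −3.68 ± 0.41. The call of LEA was lost without flowers 2 (adjusted p = 0.0514).

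The list for jasmonate synthesis and stamen, petal and nectary maturation had 3 measured members, of which 2 were higher, 0 lower and 1 did not pass (2 higher, 0 lower adjusted over the list alone). The members that rose were SWEET9 and AT3G25810, entered as TPS24, a terpene synthase, at 473 ± 90 in flowers and 19.3 ± 14.0 in buds; neither makes jasmonate. BPEp, which limits petal size, was at 89.1 and 108 (adjusted p = 0.645). An added group of 5 genes of jasmonate metabolism and signalling, with medians of 0.78, 0.13 and −0.30, did not pass in any comparison (adjusted p = 0.614 for flowers against buds, 0.285 for siliques against flowers and 0.586 for siliques against buds). Its members higher and lower were 1 and 0, 0 and 2, and 0 and 1 in these comparisons. For siliques against flowers the group mean was −0.94 despite the median of 0.13, with a downward test. The list median was 4.12 (3.42 in replicate 1 and 4.81 in replicate 2; adjusted p = 0.0199), with adjusted p = 0.399 with an estimated correlation. In the tapetum and pollen wall list 2 of 3 members fell, also adjusted over the list alone, with a median of −2.92 (−2.74 and −3.10 by replicate; adjusted p = 0.0199, and adjusted p = 0.399 with an estimated correlation). These were AT5G07230 and SWEET8, a sugar transporter needed for the pollen wall, at 73.9 ± 5.4 in flowers and 627 ± 71 in buds, whereas EMS1, a receptor kinase that sets tapetum fate, was at 202 and 165 (adjusted p = 0.370).

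In the mature pollen and pollen tube list, 0 of 5 members were higher, 2 lower and 3 did not pass (1 higher and 3 lower adjusted over the list alone). The pollen MADS-box genes AGL104 and AGL66 had log2 changes of −1.93 ± 0.29 and −1.76 ± 0.41. AGL104 lost its call without flowers 1 (adjusted p = 0.0552), and AGL66 lost it with a replicate term (0.0511), in 3 other settings (0.0575 to 0.111) and without any 1 array but buds 2 (0.0531 to 0.207). ANX2, a pollen tube receptor kinase, was at 131 in flowers and 43.6 in buds (adjusted p = 0.0709). The list median was −0.94 and the list test did not pass (adjusted p = 0.417). Flavonoid and anthocyanin synthesis had 3 measured members: DFR, dihydroflavonol reductase, rose from 15.1 ± 0.8 to 243 ± 54 (log2 change 3.31 ± 0.19), and UGT78D2 and UGT78D1 did not pass (1 higher, 0 lower adjusted over the list alone). Its test (median 0.54, adjusted p = 0.0420; adjusted p = 0.399 with an estimated correlation) passed in only 7 of 18 alternative settings, with adjusted p from 0.00585 to 0.348. It was lost without buds 1 (0.348), flowers 2 (0.113), siliques 1 (0.0561) and siliques 2 (0.0559).

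YAB3, a regulator of organ polarity and fruit pattern, fell by 1.06 ± 0.17 on the log2 scale and was the only called member of the carpel and fruit patterning list, the others being SPT and ALC (0 higher, 1 lower adjusted over the list alone). That list had a median of −0.40 and did not pass (adjusted p = 0.0743); over its alternatives adjusted p ran from 0.0256 to 0.348, and it passed with a replicate term (0.0450), without flowers 1 (0.0295) and without buds 2 (0.0256). The call of YAB3 itself was lost without flowers 1 (adjusted p = 0.0717), flowers 2 (0.0512) or buds 2 (0.0632). None of the 8 nuclear-encoded photosynthesis genes (median −0.05, adjusted p = 0.575) and none of the 6 histone genes (median −0.19, adjusted p = 0.575) passed, nor did any adjusted over the list alone. SPL (SPOROCYTELESS), which starts sporogenesis and was the only tested floral organ identity gene, was at least 6.85-fold lower in flowers, a call lost with the smaller offset (adjusted p = 0.0606). BAN, the anthocyanidin reductase of the seed coat, was at least 2.80-fold higher, a call lost with only the arrays compared (0.0555), and the integument regulator INO was at 72.6 and 71.0 (adjusted p = 0.958). SAG29, a senescence-associated sugar transporter and the only tested senescence gene, was at 527 ± 160 and 72.6 ± 9.8 (adjusted p = 0.0345); that call was lost without the filter (0.0540) and without any 1 of the 4 bud and flower arrays (0.0848 to 0.167).

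Of the added groups, 2 passed. Plastid-encoded photosynthesis genes were lower in flowers: 0 of 33 were higher, 8 lower and 25 did not pass, with a median of −0.78 (−0.36 in replicate 1 and −1.21 in replicate 2; adjusted p = 7.90e-06, and adjusted p = 0.958 with an estimated correlation). The ATP synthase gene atpA was at 82.9 ± 55.6 in flowers and 606 ± 268 in buds, atpF at 29.6 ± 10.3 and 122 ± 49, and psbB, of photosystem II, at 52.9 ± 13.6 and 130 ± 7. The calls of atpA and atpF were lost without flowers 2 (adjusted p = 0.136 and 0.147) or buds 2 (0.136 and 0.121), and that of atpF without flowers 1 (0.0587). The CYP family was grouped by its symbol stem alone. It had 3 of 7 members higher, CYP71B31, CYP71B38 (log2 change 2.83 ± 0.27) and CYP78A9 (at least 9.64-fold higher), 0 lower and 4 that did not pass. Its median was 0.57 (0.76 and 0.38 by replicate; adjusted p = 0.000361, and adjusted p = 0.958 with an estimated correlation), and the test was lost with the stricter filter (0.102; range over the alternatives 1.51e-05 to 0.102).

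At an unadjusted p under 0.05, 3022 of the 12075 probe sets differed between flowers and buds, and with a replicate term 656 were higher and 834 lower. Without flowers 1 the counts were 275 and 388, without flowers 2 219 and 361, and without buds 2 278 and 428; of the 75 named genes called, 45 lost the call without at least 1 array.

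Siliques were compared with open flowers to find what changes from the flower to the young fruit. BAN rose from 26.6 ± 13.2 in flowers to 661 ± 5 in siliques (log2 change 4.25 ± 0.26, adjusted p = 0.00154), and DFR from 243 ± 54 to 821 ± 103 (1.73 ± 0.19, adjusted p = 0.00521). RALFL28 (AT4G11510), a signalling peptide gene of the RALF family, was at least 21.6-fold higher in siliques. CYP71B31 was at least 236-fold lower in siliques, and SWEET9 fell from 1405 ± 189 to 14.7 ± 2.8 (log2 change −5.84 ± 0.46, adjusted p = 0.00218). Probe sets higher in siliques than in flowers numbered 873, and 900 were lower. The balance turned with median normalization (951 and 881), quantile normalization (746 and 695), the stricter filter (846 and 761), a replicate term (1136 and 1054) and a robust fit (874 and 854).

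The other large rises were RR22 (AT3G04280), a cytokinin response regulator, IAA31 (AT3G17600), of the auxin response, and LCR24 (AT4G29285), a cysteine-rich peptide gene. They reached signals of 259, 266 and 276 in siliques, with log2 changes of 2.98 ± 0.24, 2.65 ± 0.20 and 2.08 ± 0.23. PME61 (AT3G59010), a pectin methylesterase, rose from 31.0 ± 2.8 to 180 ± 35 (adjusted p = 0.00285). LCR24 was not past the test without siliques 1 (adjusted p = 0.0543) or with the smaller offset (0.0522). The other large falls were JMT (AT1G19640), which methylates jasmonic acid, from 659 ± 400 to 21.1 ± 1.9, and UPB1, XTH19 and LPR1. Their log2 changes were −4.29 ± 0.43, −4.04 ± 0.37, −3.96 ± 0.29 and −3.70 ± 0.23.

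All 3 measured members of the list for jasmonate synthesis and stamen, petal and nectary maturation fell, also adjusted over the list alone. AT3G25810 was at least 60.3-fold lower in siliques, and BPEp fell from 89.1 ± 14.9 to 8.61 ± 4.91. The median was −4.83 (−4.64 and −5.03 by replicate; adjusted p = 0.000117, and adjusted p = 0.157 with an estimated correlation). In the mature pollen and pollen tube list 2 of 5 members fell, also adjusted over the list alone: AT4G39110, entered as BUPS1, and ANX2, both receptor kinases of the pollen tube, with log2 changes of −1.90 ± 0.38 and −1.85 ± 0.40. The list median was −0.93 (−1.57 and −0.91 by replicate; adjusted p = 0.00833, and adjusted p = 0.384 with an estimated correlation). AT4G39110 lost its call without flowers 1 (adjusted p = 0.118), flowers 2 (0.0993) or siliques 1 (0.114). ANX2 lost it without any 1 of the 4 flower and silique arrays (0.0558 to 0.155) and without the filter (0.0564).

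Nuclear-encoded photosynthesis genes were higher in siliques: 4 of 8 rose, 0 fell and 4 did not pass (6 higher, 0 lower adjusted over the list alone), with a median of 0.59 (0.64 and 0.49 by replicate; adjusted p = 0.000857, and adjusted p = 0.384 with an estimated correlation). LHCB4.2, a light-harvesting protein, was at 976 ± 91 in siliques and 551 ± 53 in flowers, and PSAN, PSAE-1 and PSBY, of the photosystems, had log2 changes of 0.74 ± 0.13, 0.60 ± 0.15 and 0.58 ± 0.15. PSAE-1 and PSBY were not past the test with cyclic loess (adjusted p = 0.282 and 0.160) or quantile normalization (0.214 and 0.119), without the filter (0.105 and 0.102) or without the trend (0.0575 and 0.0594), nor was PSBY with only the arrays compared (0.0661) or without buds 1 (0.0638) or buds 2 (0.0650). All 4 genes lost their calls without any 1 of the flower and silique arrays (0.0576 to 0.256). DFR was the only called flavonoid gene (2 higher, 1 lower adjusted over the list alone), and that list did not pass (median 1.00, adjusted p = 0.351). Nor did the histone list, in which the male gamete histone MGH3 alone fell, also adjusted over the list alone (median 0.17 but mean −0.08, with an upward test; adjusted p = 0.735); the call of MGH3 was lost with quantile normalization (0.0644), without the filter (0.0607) and without flowers 1 (0.139), flowers 2 (0.132) or siliques 1 (0.151). No carpel and fruit patterning gene passed (median −0.19, adjusted p = 0.735; 0 higher, 1 lower adjusted over the list alone) and no tapetum gene passed by either adjustment (median 0.10, adjusted p = 0.895). GH3.3, which conjugates auxin, rose from 194 ± 33 to 469 ± 45 (log2 change 1.24 ± 0.19), and WES1, the other tested auxin response gene, was at 170 and 189 (adjusted p = 0.851). The mitotic kinases AUR1 and AUR2, at 102 and 70.3 in siliques and 139 and 92.7 in flowers, did not pass (adjusted p = 0.0918 and 0.151; 0 higher, 2 lower adjusted over the list alone). SAG29 was at 154 ± 138 in siliques and 527 ± 160 in flowers (adjusted p = 0.0676; lower adjusted over its list alone, of which it was the only tested member). The call of GH3.3 was lost without any 1 of the flower and silique arrays (adjusted p = 0.0502 to 0.0825).

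The added groups held 8 past the test, each with adjusted p = 0.691 with an estimated correlation. Nuclear-encoded chloroplast photosynthesis proteins, which include the listed photosynthesis genes, had 12 of 24 members higher, 0 lower and 12 that did not pass (median 0.59, adjusted p = 8.82e-06). CaS, a thylakoid calcium-binding protein, had the largest change among them, from 243 ± 55 to 578 ± 3, and NdhN, of the NDH complex, rose from 142 ± 10 to 281 ± 23. Of the plastid-encoded photosynthesis genes 7 of 33 were higher, 0 lower and 26 did not pass, with a median of 0.80 (0.26 in replicate 1 and 1.14 in replicate 2; adjusted p = 3.93e-05). Examples were ndhI at 1451 ± 88 in siliques and 655 ± 123 in flowers, and psbH at 839 ± 93 and 355 ± 51. Against buds the group showed no such rise: 0 of 33 passed in siliques, with a median of −0.16 (adjusted p = 0.879 by camera). Plastid-encoded gene-expression genes had 5 of 15 higher, 0 lower and 10 that did not pass (median 0.99, by replicate 0.75 and 1.15; adjusted p = 2.19e-05), such as the ribosomal protein gene rpl16 at 144 ± 7 and 44.9 ± 18.9 and the polymerase gene rpoA at 499.7 ± 13.3 and 246 ± 30. In tetrapyrrole and chlorophyll synthesis 6 of 10 rose, 0 fell and 4 did not pass (median 0.87, adjusted p = 0.000113), led by CHLI2, of magnesium chelatase, from 82.6 ± 17.4 to 210 ± 2, and HEME1, a uroporphyrinogen decarboxylase, from 134 ± 3 to 326 ± 9. Each of these 8 gene calls was lost without at least 1 array (highest adjusted p from 0.0671 to 0.122).

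The other 4 added groups passed by smaller margins. The TBL family, cell wall acetylation proteins, had 4 of 12 higher, 0 lower and 8 that did not pass (median 0.46, adjusted p = 0.0345), with TBL36 at 255 ± 77 in siliques and 84.0 ± 3.1 in flowers; without siliques 1 the adjusted p was 0.104. The CYP family had 0 higher, 3 lower and 4 that did not pass (median −0.41, adjusted p = 0.0125). Those lower were the same 3 genes that were higher in flowers than in buds. CYP78A9 lost its call without flowers 1 (0.0886), flowers 2 (0.0835) or siliques 1 (0.0633). Among the sugar transporters with a SWEET symbol 1 of 12 was higher, 5 lower and 6 did not pass (median −1.43, adjusted p = 0.0434). Over the alternatives the adjusted p ran from 0.0171 to 0.0957, the highest with a replicate term. Family members listed under other symbols were not counted. SWEET11 fell from 869 ± 6 to 193 ± 97 and SWEET1 from 865 ± 28 to 288 ± 14, while SWEET7 rose from 73.3 ± 8.1 to 210 ± 18; without flowers 2 the group was not past the test (0.0603). Cold and dehydration genes had 0 of 8 higher, 4 lower and 4 that did not pass (median −0.72, adjusted p = 0.0499; range 0.00588 to 0.125), with COR47 at 337 ± 41 in siliques and 2435 ± 56 in flowers. The group test, unlike the call of COR47, was lost with a replicate term (0.0608), the larger offset (0.0519) and the stricter filter (0.0587). It was also lost without flowers 1 or siliques 2. The group median ran from −1.16 to −0.56 over the alternatives. The calls of TBL36, SWEET11 and COR47 were lost without at least 1 array (highest adjusted p = 0.0704 without flowers 2, 0.0711 without flowers 1 and 0.0979 without siliques 1).

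At an unadjusted p under 0.05, 3813 probe sets differed between siliques and flowers. Without flowers 1 the counts were 114 and 235, without flowers 2 106 and 166, without siliques 1 80 and 171, and without siliques 2 224 and 441; without the filter on dim probe sets 533 were higher, and 78 of the 99 named genes called lost the call without at least 1 array.

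**Figure D1:**
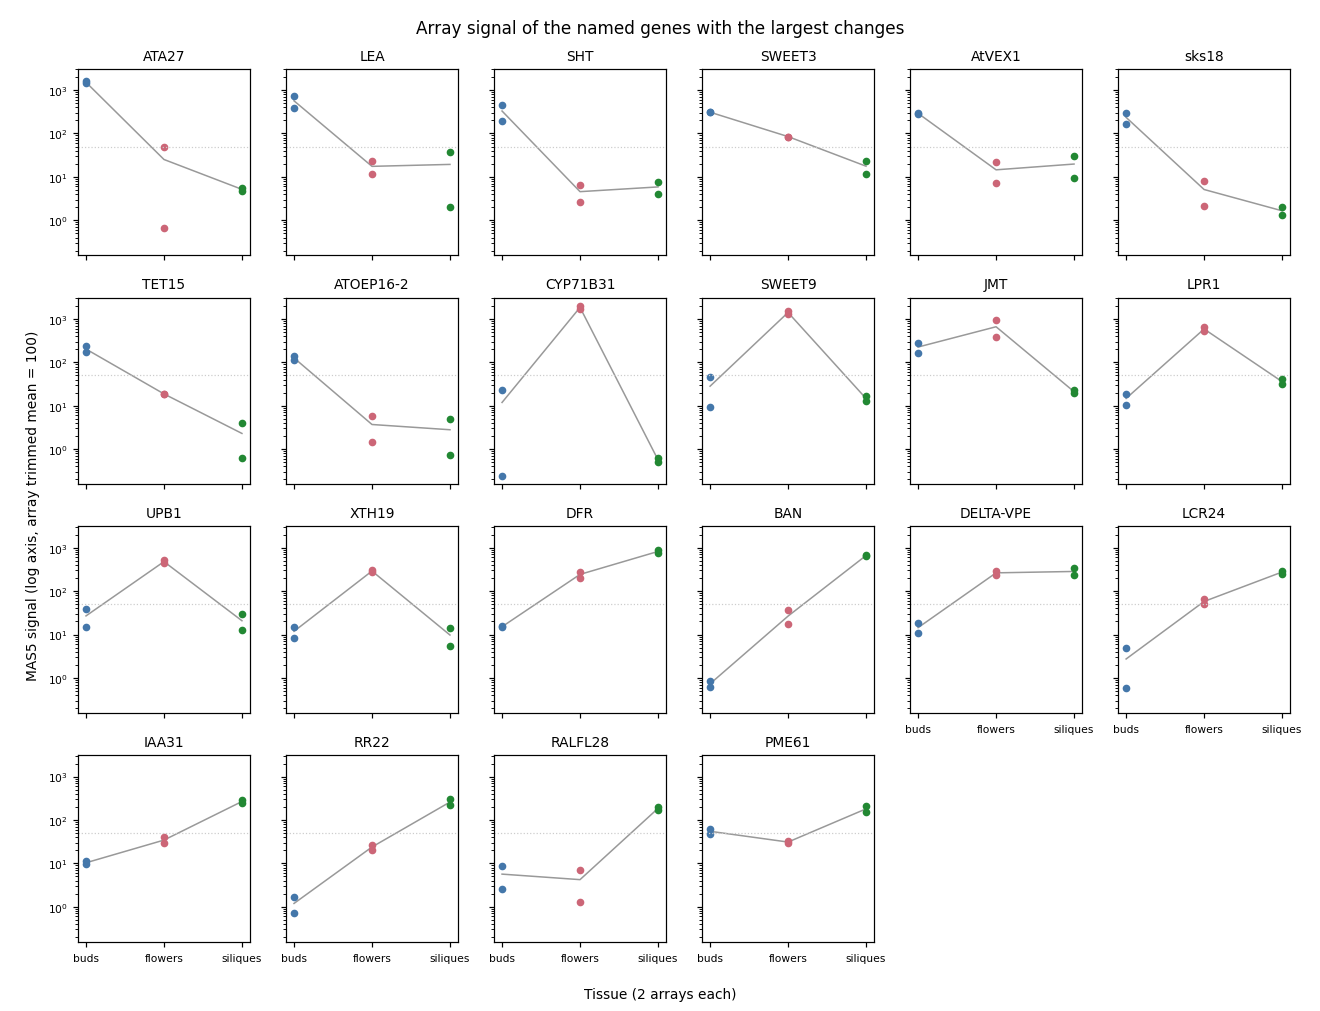
Signal (log axis) of 22 named genes in buds, flowers and siliques; each point is an array, the grey line joins the group means and the dotted line marks the filter at a signal of 50. SWEET9 stands at 1405 in flowers against 28.1 in buds and 14.7 in siliques, and BAN at 661 in siliques against 26.6 in flowers.

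Siliques were compared with buds to span the whole interval from before pollination to the young fruit. BAN was at least 74.5-fold higher in siliques, at 661 ± 5, and DFR rose from 15.1 ± 0.8 to 821 ± 103 (log2 change 5.04 ± 0.19, adjusted p = 0.000126). RR22 was at least 28.8-fold, LCR24 at least 30.9-fold and RALFL28 at least 20.7-fold higher, and IAA31 rose by 3.76 ± 0.20 on the log2 scale. ATA27 was at least 194-fold lower in siliques, and AT5G07230 at least 105-fold lower. In siliques 849 probe sets were higher and 1029 lower than in buds. The balance turned with median normalization (1092 and 916), quantile normalization (896 and 833), the stricter filter (724 and 704) and a replicate term (1217 and 1210).

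Further large falls were in sks18 (at least 28.9-fold), SHT (at least 38.6-fold) and TET15 (AT5G57810), a tetraspanin (at least 25.6-fold). LEA and the sugar transporter SWEET3 (AT5G53190) had log2 changes of −4.52 ± 0.64 and −3.56 ± 0.22. In the mature pollen and pollen tube list 0 of 5 members were higher, 3 lower and 2 did not pass (0 higher, 4 lower adjusted over the list alone). AGL66, AGL104 and the pollen actin ACT12 had log2 changes of −2.69 ± 0.41, −2.52 ± 0.29 and −1.54 ± 0.27; the list median was −1.54 (−2.11 and −1.65 by replicate; adjusted p = 0.00469, and adjusted p = 0.309 with an estimated correlation). ACT12 was not past the test with cyclic loess (adjusted p = 0.0631) or quantile normalization (0.0524), or without siliques 1 (0.0572) or siliques 2 (0.0655). In the tapetum and pollen wall list AT5G07230 and SWEET8 fell, also adjusted over the list alone, and EMS1 was at 216 and 165 (adjusted p = 0.184). Its median was −2.95 (−2.78 and −3.11 by replicate; adjusted p = 0.0357, and adjusted p = 0.309 with an estimated correlation), and over the alternatives its adjusted p ran from 0.00760 to 0.0622, the highest with a replicate term; without buds 2 it was 0.0515.

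Photosynthesis genes encoded in the nucleus had 3 of 8 members higher and 0 lower, also adjusted over the list alone, and 5 that did not pass (median 0.46, by replicate 0.48 and 0.54; adjusted p = 0.00469, and adjusted p = 0.309 with an estimated correlation). This list was not past the test with quantile normalization (0.276) or cyclic loess (0.483; range over the alternatives 0.00343 to 0.483). The 3 genes were PSAE-1, PSAN and PSBY, with log2 changes of 0.68 ± 0.15, 0.59 ± 0.13 and 0.57 ± 0.15; their calls were lost with quantile normalization, cyclic loess, no filter or only the arrays compared (adjusted p = 0.0639 to 0.400), and without any 1 array except, for PSAE-1, buds 1 (0.0658 to 0.171). The flavonoid list had 1 member higher, DFR (2 higher, 0 lower adjusted over the list alone), and a median of 1.13 (adjusted p = 0.0565, range 0.0173 to 0.164; 0.0322 without siliques 1 and 0.0173 without buds 2). The jasmonate, petal and nectary list had 1 member lower by both adjustments, BPEp, with a log2 change of −2.67 ± 0.27 (median −0.72, adjusted p = 0.0591, range 0.00875 to 0.355, the lowest without buds 2). YAB3 fell by 1.68 ± 0.17 on the log2 scale, the only called carpel and fruit patterning gene by either adjustment (median −0.59, adjusted p = 0.145). MGH3 fell by 2.96 ± 0.40, the only called histone gene by either adjustment (list median 0.18 but mean −0.32, with an upward test; adjusted p = 0.809). The mitotic kinases AUR1 and AUR2 were at 102 and 70.3 in siliques and 149 and 97.8 in buds (adjusted p = 0.0518 and 0.0969; 0 higher, 2 lower adjusted over the list alone). The replication genes ICU2 and PRL (adjusted p = 0.164 and 0.486) and the gibberellin receptor GID1A (0.457) did not pass.

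The added groups past the test numbered 5, each with adjusted p = 0.928 with an estimated correlation. Pollen-expressed genes, which include the called members of the pollen list, had 0 of 20 higher, 8 lower and 12 that did not pass (median −0.83, by replicate −1.69 and −0.39; adjusted p = 0.000460). AtVEX1 fell from 290 ± 9 to 19.7 ± 14.6, MGH3 from 154 ± 72 to 11.2 ± 9.7, the cation exchanger gene CHX19 from 210 ± 6 to 21.8 ± 0.7, and the myosin gene XIE from 133 ± 4 to 12.6 ± 1.2. In tetrapyrrole and chlorophyll synthesis 5 of 10 were higher, 0 lower and 5 did not pass (median 0.82, adjusted p = 0.000460), with CHLI2 at 210 ± 2 and 72.6 ± 8.7 and GSA1, an early enzyme of the pathway, at 485 ± 44 and 203 ± 64; GSA1 lost its call without siliques 1 (0.0654) or siliques 2 (0.0927). Nuclear-encoded chloroplast photosynthesis proteins had 8 of 24 higher, 0 lower and 16 that did not pass (median 0.46, adjusted p = 0.000460); the test was lost with quantile normalization (0.0965) and cyclic loess (0.0958; range 4.01e-05 to 0.0965). Cold and dehydration genes had 4 of 8 lower, LEA, COR15A, DI21 and DI19 (median −1.14, adjusted p = 0.00913), and 4 that did not pass. SWEET transporters, again only those with that symbol, had 4 of 12 lower, SWEET3, SWEET14, SWEET8 and SWEET1, and 8 that did not pass (median −0.83, adjusted p = 0.0170). With a replicate term the adjusted p was 0.0504, the highest of a range from 0.00364. SWEET14 and DI21 lost their calls without buds 1 (adjusted p = 0.0803 and 0.0505), siliques 1 (0.125 and 0.0539) or siliques 2 (0.0751 and 0.0549).

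At an unadjusted p under 0.05, 3930 probe sets differed between siliques and buds. Without buds 1 the counts were 388 and 602, without siliques 1 307 and 564, without siliques 2 288 and 586, and without flowers 2 564 were higher; 35 of the 74 named genes called lost the call without at least 1 array.

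**Figure D2:**
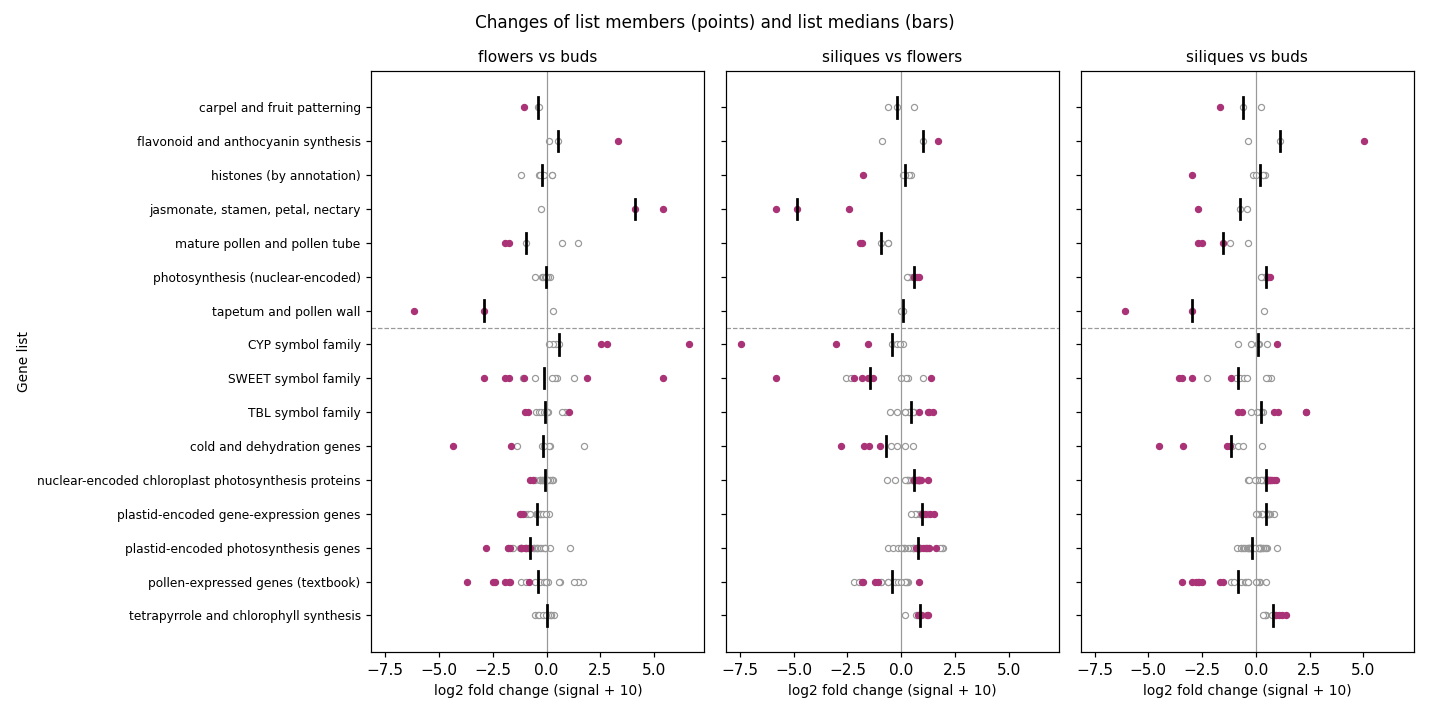
Log2 change of each measured member of 16 gene lists in the 3 comparisons; filled points passed the test, open points did not, bars are list medians, and the dashed line parts the 7 lists fixed beforehand from the 9 added groups. Plastid-encoded photosynthesis genes have a median of −0.78 for flowers against buds and 0.80 for siliques against flowers.

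Changes in opposite directions were the most frequent among probe sets called in both successive comparisons: 272 were higher in flowers than in buds and then lower in siliques, where 40.8 would be shared if the calls were independent. A further 105 were lower and then higher (53.5), 55 were higher both times (39.5) and 60 lower both times (55.2). In 100 simulations in which the changes of the comparisons were unrelated but the flower arrays shared, set up after the counts were seen, 44 to 87 were higher and then lower, 27 to 62 lower and then higher, 19 to 43 higher both times and 46 to 80 lower both times. The flower arrays serve in both comparisons, which favours opposite signs. With flowers 1 set against buds and flowers 2 against siliques, a division chosen after the counts were seen, 62 were higher and then lower (4.26 if independent), 12 lower and then higher (3.41), 17 higher both times (2.07) and 17 lower both times (7.03). With flowers 2 set against buds and flowers 1 against siliques these were 76 (3.78), 8 (3.41), 21 (2.41) and 17 (5.33). Both fits of a division take the spread of each probe set from the same bud and silique arrays, which favours shared calls of every kind. Every kind exceeded its value if independent, so these values are too low a yardstick. Among genes with a symbol, 30 went up and then down, including CYP71B31, SWEET9, LPR1, UPB1, XTH19, CES (1.52 and −3.20) and BETA-VPE (1.08 and −2.41). Those higher both times were 8, among them DFR, LCR24, BAN, RR22 and IAA31. The 13 that were lower and then higher included SWEET7 and the plastid genes rpl16, psaA and ndhI. The 5 lower both times were TET15, SWEET3, COR15A, OCT1 and HHP2. Probe sets lower and then higher became fewer than those of either same-direction kind without flowers 1, siliques 1 or buds 2. The same held at an adjusted p under 0.01. Probe sets higher and then lower numbered 110 without flowers 1, 63 without flowers 2, 95 without siliques 1, 153 without buds 2 and 177 without siliques 2.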

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

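The tests on the added groups, and their alternatives, were chosen after the gene table was seen; added groups not past the test were not followed further. For gene lists the value followed was changed from the median to the adjusted p after the first output was seen. Of the 248 named gene results, 176 kept their direction and their call in each alternative that gave them a value with all arrays (the stricter filter did for 210) and 87 also with any 1 array left out, and none reversed; an adjusted p under 0.01 kept 107 and a 2-fold change 183; the most calls were lost without the filter (55 of 248) and without flowers 2 (122). The called added groups kept their directions throughout. No scaling reversed a called list or gene. Signals near background limit the folds of dim genes to lower bounds.

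With an adjusted p under 0.01, a stricter threshold, the counts higher and lower were 226 and 346 (flowers against buds), 108 and 194 (siliques against flowers) and 273 and 511 (siliques against buds). With a 2-fold change also required, 304 were higher and 673 lower in siliques than in flowers, and 389 higher and 756 lower than in buds. Without the filter 533 were higher in siliques than in flowers; the cause was not tested. The shared calls higher both times, higher then lower, lower then higher and lower both times were 15, 72, 11 and 16 at the stricter threshold. Without the filter those higher both times, lower then higher and lower both times were 36, 57 and 38 (the cause was not tested), and with a 2-fold change those higher both times and lower then higher were 34 and 37. With 1 array left out, fewer arrays gave 219 to 567 higher and 361 to 640 lower in flowers against buds, 80 to 970 and 166 to 1066 in siliques against flowers, and 288 to 789 and 564 to 1019 in siliques against buds. The 4 kinds of shared calls then ran from 13 to 49, 63 to 355, 11 to 90 and 12 to 49. With the flower arrays divided between the comparisons, a choice made after the counts were seen, fewer arrays gave 17, 62, 12 and 17 (flowers 1 against buds) and 21, 76, 8 and 17 (flowers 2 against buds).

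The flavonoid list (adjusted p = 0.0420, flowers against buds) was at 0.0543 with the larger offset, 0.259 without the filter, 0.0647 with the stricter filter, 0.0630 with quantile, 0.0556 with median and 0.0586 with cyclic loess normalization, and 0.0597 with only the arrays compared. The photosynthesis list, siliques against buds, was at 0.276 with quantile and 0.483 with cyclic loess normalization. A replicate term gave 0.0450 for the carpel list (flowers against buds) and 0.0622 for the tapetum list (siliques against buds). The cause of these changes was not tested. With an estimated correlation no list passed: adjusted p = 0.399 for the petal and nectary, tapetum and flavonoid lists (flowers against buds), 0.157 for petal and nectary and 0.384 for pollen and photosynthesis (siliques against flowers), and 0.309 for pollen, photosynthesis and tapetum (siliques against buds).

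With 1 array left out, adjusted p ran from 0.00585 to 0.348 for the flavonoid, 0.0256 to 0.348 for the carpel, 0.266 to 0.824 for the photosynthesis and 0.348 to 0.984 for the histone list (flowers against buds). For siliques against flowers it ran from 0.614 to 0.986 (carpel) and 0.786 to 0.992 (tapetum), and for siliques against buds from 0.0173 to 0.123 (flavonoid), 0.00875 to 0.355 (petal and nectary) and 0.0139 to 0.0515 (tapetum). The median changed sign, with no test passed, for photosynthesis without flowers 1 (0.824) and histones without buds 2 (0.984), flowers against buds, and for carpel without flowers 1 (0.986) and tapetum without flowers 2 (0.948), siliques against flowers.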

Other observations

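The test of a later harvest stage in buds 1 was chosen before its result was seen; the other tests below were chosen after the results they concern.

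The 2 bud arrays differed more from each other than the arrays of the other stages: the SD of the log2 difference between replicates was 0.44 for buds, 0.35 for flowers and 0.39 for siliques. Genes known from late pollen were among those higher in buds 1, such as the LIM protein gene PLIM2a at 668 against 216, the pectate lyase gene AT59 at 204 against 58.5 and the expansin gene EXPB5 at 223 against 58.7. On the flower arrays they were higher than on both bud arrays (PLIM2a 990 and 911, AT59 370 and 407, EXPB5 387 and 467). They were picked for their large differences between the bud arrays. SWEET14 was at 616 and 141 in buds and at 80.4 and 222 in flowers. COR47 was at 1272 and 411 in buds and at 2475 and 2396 in flowers. CCL, at 1007 in buds 1 and 110 in buds 2, was also higher in flowers 1 (654) than in flowers 2 (240). SHT, at 195 in buds 1 and 463 in buds 2, and TOPII, at 51.8 and 160, differed the other way. So did the plastid genes rps2 (47.1 and 163), matK (692 and 1523), ndhA (161 and 363), rpl32 (369 and 802) and rps19 (278 and 601). The median change of plastid-encoded gene-expression genes from buds to flowers was −0.07 in replicate 1 and −0.87 in replicate 2. The linker histone gene HIS1-3 was below the filter, with a signal of 222 in buds 1 and 15.3 in buds 2.

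The pollen-expressed genes were higher in buds 1 than in buds 2 for 15 of 20 members, with a median difference of 0.27 (95% bootstrap interval over genes 0.06 to 0.77). If buds 1 had held more anther tissue, early anther transcripts should be higher there too. The 267 probe sets at least 4-fold lower in flowers than in buds had a median difference of −0.136 (−0.220 to −0.0871). They were not chosen as anther transcripts, and a later stage of buds 1 could lower them whatever its share of anthers. More anther tissue is therefore not decided by this test. A candidate explanation is that buds 1 was harvested slightly later: across the 1287 probe sets called between flowers and buds, the difference buds 1 minus buds 2 correlated with flowers minus buds at r = 0.466 (0.412 to 0.515; Spearman 0.407), although genes are not independent replicates and the bud arrays enter both sides. With the labels of the bud arrays swapped at random per probe set, 1000 times, r ran from −0.115 to 0.129. These swaps treat probe sets as independent, so the range does not cover a difference of stage, handling or run shared by many genes. If all the noise lay in buds 2, the shared arrays alone would give 0.113. The 164 probe sets at least 4-fold higher in flowers had a median difference of 0.44 between the bud arrays. The pollen-expressed genes themselves went the other way: 0 of 20 were higher and 7 lower in flowers than in buds, with a median of −0.41. Adjusted over the group alone, 3 were higher and 10 lower. By the median a later harvest would lower them in buds 1, where they were higher. Because members moved both ways, the median of the set cannot decide on a later harvest. With 1 array per replicate and stage a later harvest remains a hypothesis, and an effect of handling or hybridisation on a single bud array stays open. So does a difference between the runs as a whole: across the tested probe sets the replicate differences of buds and flowers correlated at 0.34, and those of buds and siliques at −0.01. The median of the pollen-expressed genes was −0.11 (−0.30 to 0.04) for flowers 1 minus flowers 2.

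Plastid-encoded photosynthesis genes were lower in flowers than in buds, with a median of −0.78 (−0.98 to −0.48), but 25 of 33 did not pass. The adjusted p of the group's camera test was 7.90e-06 at the preset and 0.958 at an estimated correlation. The intervals are bootstraps over probe sets and hold no spread between arrays. Both medians within a replicate, −0.36 and −1.21, lay outside that of −0.98 to −0.48. A lower share of green tissue in flowers should lower nuclear-encoded photosynthesis genes by about as much, but their median was −0.0541 (−0.232 to 0.00459). Within replicate 1 the nuclear median was −0.13 (−0.28 to −0.09), against −0.36 (−0.52 to −0.21) for the plastid genes, and these intervals overlap. Within replicate 2 the medians were −0.05 (−0.17 to 0.12) and −1.21 (−1.60 to −0.62). The pooled values and those of replicate 2 argue against a lower share of green tissue, whereas replicate 1 alone does not decide it. A single bud array with high plastid signal is argued against as the whole cause for the photosynthesis genes, the only plastid genes put to this test. The bud arrays would then have to differ by 1.57, and the median of buds 1 minus buds 2 was −0.202 (−0.570 to −0.0526). Flowers were lower than buds 1 alone by 0.74 and than buds 2 alone by 0.90. The flower arrays differed more, flowers 1 being higher than flowers 2 by 0.57, and the median was −0.36 within replicate 1 and −1.21 within replicate 2. A difference between arrays in how much organelle RNA was labelled might account for it and cannot be told apart, because the median of the mitochondria-encoded probe sets was −0.354 (−0.710 to −0.122) and only 4 dim ones were measured. A biological difference between the stages, whose organs differ by design, was not separated from these and stays open. The rise of the plastid-encoded photosynthesis genes from flowers to siliques rests on the same flower arrays, so the same limits hold for it.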
